A study of Mus musculus with 90 samples.

How the data were processed

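Liver RNA from 90 female Diversity Outbred mice, an outbred stock in which each animal carries its own mixture of founder strain genomes, was measured by RNA sequencing, with 1 library per animal. Of these animals, 41 were given sterile distilled water by mouth and 49 were given zileuton, an inhibitor of the enzyme 5-lipoxygenase, at 300 mg per kg, daily over 7 days. Animals were 6 to 20 weeks old, and RNA came from 25 mg of liver. RNA with an integrity number below 8 was excluded, per the labels. Libraries were made with the TruSeq RNA kit and read on an Illumina HiSeq instrument, per the labels.

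The deposited raw table holds an expected count per gene and animal, that is, an estimated count in which reads shared between features were divided. Of these values, 77.1% were whole numbers and none was below 0. The second deposited table holds a signal per gene made by the authors, in which the estimated counts of each animal were rounded and divided by 1 size factor. After rounding, the ratio between the tables was constant within each library to within a relative deviation of 5.0e-06 over values above 50 counts. The submitters' processing notes name Partek, STAR, DESeq2 and the build mm10, without versions. The counting tool, its annotation and the strand setting are not given in the sources used here.

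The tables hold 18223 genes by symbol, of which 17848 (97.9%) matched 1 gene of that symbol in GENCODE release M21 (build GRCm38, which is mm10), the source of the coordinates. The tables hold 0 mitochondrially encoded genes, so the planned share of mitochondrial counts could not be computed, and 0 of the 4 Y-linked genes looked for. Total estimated counts per library ran from 12664579 to 41360187 with a median of 25535799. At these totals the precision of an expressed gene was set by the spread between animals, with a common biological coefficient of variation, fitted over all tested genes, of 32.1%. The closest pair of libraries differed by a chi-square of 46.8 per gene, so no library was a copy of another.

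Estimated counts were rounded to whole numbers for the count models. The comparison of zileuton with vehicle used the edgeR 4.0.16 quasi-likelihood F test with TMM normalization, robust dispersion and the filterByExpr filter, which left 13248 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls with at least a 2-fold change were counted too. Adjusted p-values without another tool named beside them come from this test, and all tests were two-sided. Values per gene are CPM, counts scaled to library size with TMM factors, as mean ± SD over 41 vehicle or 49 zileuton animals. Standard errors (SE) are of the log2 fold change.

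Of 32 gene lists, 30 with at least 4 measured members were tested with camera from limma 3.58.1, at its preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. No gene was in more than 1 list. A list score was the mean over members of log2 CPM scaled over all animals, or within an arm for correlations, and its difference between groups was tested with 100000 permutations. Spread between animals was tested with limma on absolute deviations from the group median of log2 CPM (prior count 2), for 11857 genes with a mean log2 CPM of at least 0. Coat colours (white and black against agouti) were compared in 1 edgeR fit with treatment as a term, followed by the interaction of treatment with coat colour. The share of variance between groups was tested by permutation of Euclidean distances.

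The rule for named genes considered those past the threshold with a mean CPM of at least 1 and group medians that differed in the direction of the fold. It named the 12 with the largest change and the 3 with the lowest p in each direction. In each list it named the 2 members with the largest change in each direction, or the most abundant member where none passed. Alox5, Alox5ap, Cyp1a2, Cyp3a11, Gpt and Got1 were always named, with up to 8 genes per direction for spread and 5 per coat colour contrast. Of the genes chosen by the rule, 2 are not reported here. The permutation test of list score differences between groups was added later. The lists, the other tests, the rule and the first set of alternatives were chosen before the data were examined.

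Alternatives covered the scaling, the low-count filter, the tool (DESeq2 1.42.0, limma-voom with quality weights), the authors' normalized values with 2 pseudocounts, and covariates. The covariates were coat colour, library plate row and column, 23 surrogate variables from sva 3.50.0, and the run of 50 consecutive animal numbers to which an animal belonged (8 runs). The labels do not say what these runs were. Also tried were leaving out the 9 libraries of lowest total or each run, and removing a GC content and gene length trend (mgcv 1.9.3). Added after seeing the data were the clock score and the animal number within its run as covariates, leaving out or setting aside the ribosomal RNA precursor Rn45s, leaving out 2 libraries with skeletal muscle transcripts, leaving out 2 libraries that lay on the other group's side, and leaving out each library in turn.

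The pipeline was tested on simulated data with the dispersions of these libraries. It recovered 95.5% of genes raised or lowered 2-fold, 91.0% at 1.5-fold and 79.1% at 1.25-fold, with 5.35% false calls. Genes were drawn independently there, with no variation shared between genes, so these rates may not hold for the real libraries. Sequence variants, the clinical data of the animals and reads themselves were not used here. Where genes are near copies of each other (the Cyp2c, Cyp3a, Cyp4a, Gsta, Gstm, Mup, Saa, Serpina1 and haemoglobin families), reads could be shared between them, and a value for 1 member may hold reads of others.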

Results

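The livers of 90 female Diversity Outbred mice were profiled by RNA sequencing after 7 days of oral vehicle (41 animals) or zileuton at 300 mg per kg (49 animals). The series title gives liver toxicity of zileuton as the subject. Coats were agouti in 29 vehicle and 34 zileuton animals, black in 6 and 6, and white in 6 and 9. Each library held between 12664579 and 41360187 estimated counts with a median of 25535799. Genes are identified by symbol, and positions are on mm10.

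The liver transcriptome differed broadly between zileuton and vehicle animals, with genes of drug metabolism, fatty acid oxidation and cell division higher and genes of protein folding and plasma proteins lower. As lists these passed camera with its preset correlation, but of them only the drug metabolism list of CAR and PXR targets passed with an estimated one. Cyp2c29, a drug-metabolising cytochrome P450 (chromosome 19, 39269405 to 39330713), rose from 2650 ± 2518 to 8755 ± 3073 CPM and lay above the vehicle median in 49 of 49 zileuton animals (log2 fold change 1.72 ± 0.15 SE, adjusted p = 1.24e-15). Dnmt3b, a DNA methyltransferase (chromosome 2, 153649450 to 153687730), fell from 6.05 ± 2.06 to 2.16 ± 0.951 CPM and lay below the vehicle median in 49 of 49 animals (log2 fold change −1.48 ± 0.13 SE, adjusted p = 7.87e-16). Of 13248 genes tested by the edgeR quasi-likelihood test, 3878 were called, 1914 higher and 1964 lower, and 184 of them changed at least 2-fold. With the run of animal numbers as a covariate, 4046 genes were called. With 2 covariates that follow the groups and were chosen after seeing the data, a score of clock genes and the position of the animal number within its run, 384 and 217 were called, and 349 and 474 of the 3878 had the other sign.

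The largest increases were in Cyp2c53-ps, a P450 pseudogene, at log2 fold change 3.09 ± 0.31 (SE, 8.54-fold), Ciart, a clock repressor, at 2.88 ± 0.36, Cyp2c55 at 2.81 ± 0.37 and Cyp4a12a, a P450 abundant in male mouse liver, at 2.56 ± 0.55. Next came Ckap2 at 2.35 ± 0.40 and Hmmr at 2.32 ± 0.39, which, like Cenpf, the last of the 12, at 2.03 ± 0.30, encode proteins of the mitotic spindle and kinetochore. Dbp rose by 2.27 ± 0.42, Gm3776 by 2.26 ± 0.42, Usp2 by 2.24 ± 0.28, Mogat1, an enzyme of triglyceride assembly, by 2.23 ± 0.28, and Ptgfr, the prostaglandin F receptor, by 2.11 ± 0.31. Adjusted p for these 12 genes was at most 1.43e-04. Leaving out vehicle replicate 15 alone moved Ckap2 to 3.14, Hmmr to 2.99 and Gm3776 to 2.92. Leaving out vehicle replicate 37 moved Cyp2c55 to 3.78. Pgrmc1, a haem-binding membrane protein, and Klf16, a transcription factor, followed Cyp2c29 in lowest p among rising genes, at 0.42 ± 0.042 and 0.72 ± 0.071 (adjusted p = 3.86e-13 for both).

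The largest decreases were in Slc34a2, a phosphate transporter, at log2 fold change −2.53 ± 0.33 (SE), the acute phase genes Saa2 at −2.50 ± 0.47 and Saa1 at −2.08 ± 0.43, and Npas2, a clock activator, at −2.35 ± 0.33. Ptgds, a prostaglandin D synthase, was at −2.14 ± 0.35, the early response factor Egr1 at −2.08 ± 0.34 and Nat8f7 at −1.99 ± 0.35. Fgf21, a hormone made by the liver, was 3.99-fold lower. Arntl, the clock factor also called Bmal1, was at −1.73 ± 0.21, the organic anion transporter Slc22a7 at −1.68 ± 0.21 and the nuclear receptor gene Ppard at −1.52 ± 0.17. Adjusted p for these 11 genes was at most 8.83e-05. Saa1 and Saa2 lay below the vehicle median in 33 and 32 of 49 zileuton animals. Without vehicle replicate 9 they stood at −1.11 and −1.39. Ankrd23, a muscle gene, was at −2.41 ± 0.42 (adjusted p = 4.42e-06) with all libraries and at −0.01 (adjusted p = 0.987) without vehicle replicate 8, a library that held skeletal muscle transcripts. Pnrc1, a nuclear receptor coregulator, and Gfod2 followed Dnmt3b in lowest p among falling genes, at −0.78 ± 0.079 and −0.73 ± 0.071 (adjusted p = 8.78e-13 and 3.86e-13).

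Gene lists asked which functions moved together. Camera with its preset correlation placed 14 of 30 lists past the threshold, 8 higher and 6 lower with zileuton. A permutation test of list scores, not planned beforehand, placed 12 (8 higher, 4 lower). With an estimated correlation, CAR and PXR targets alone passed. Of 100 splits of the 90 libraries, the real one included, 6 gave at least 14 lists by camera, so members and scores stand beside each call.

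**Figure D1:**
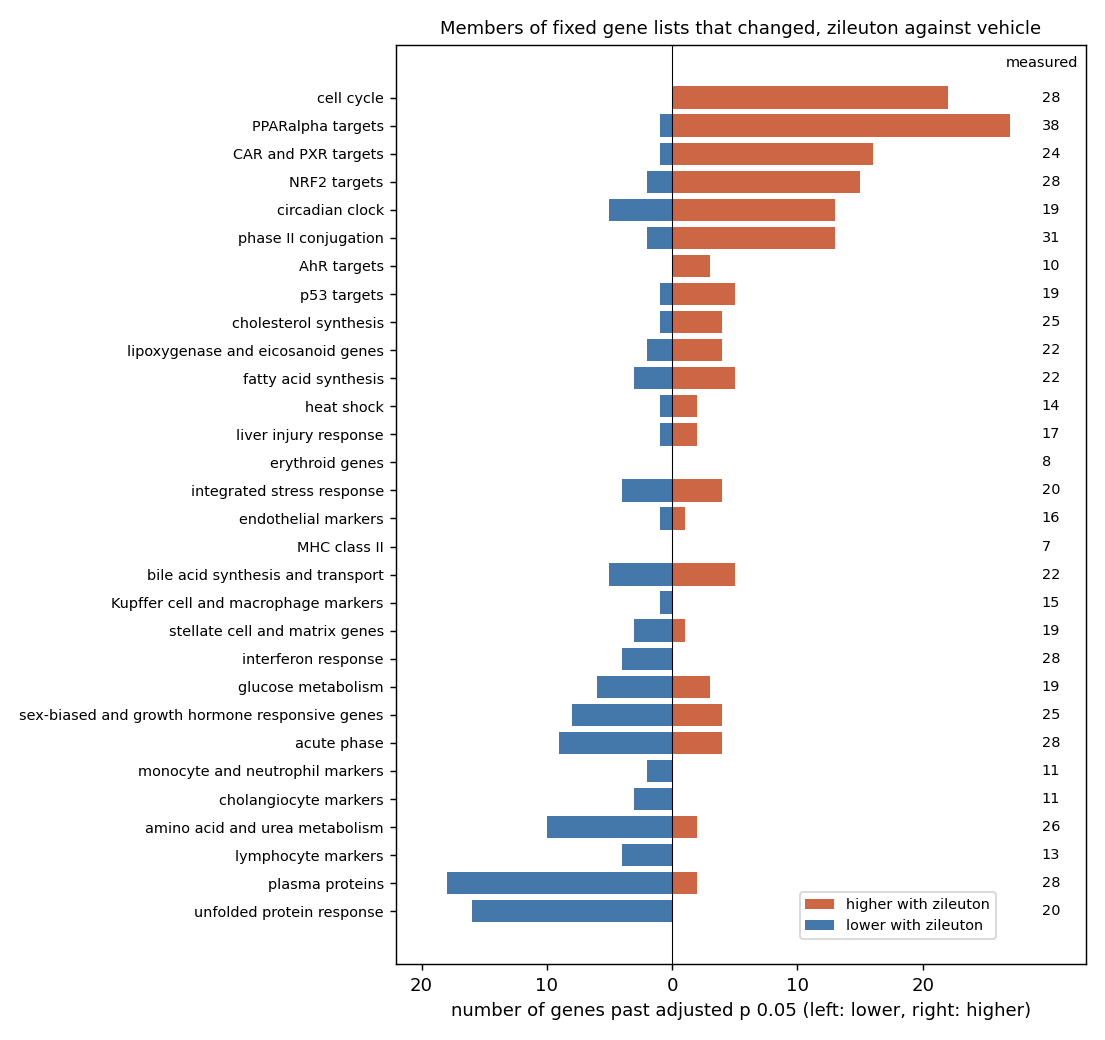
Number of members of each of 30 gene lists past adjusted p 0.05 (horizontal axis, edgeR quasi-likelihood), to the right where higher and to the left where lower in 49 zileuton than in 41 vehicle animals, with the number measured at the right edge. The cell cycle list had 22 of 28 members higher and the unfolded protein response list 16 of 20 lower.

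Genes of drug metabolism rose. Of the targets of CAR and PXR, the nuclear receptors that sense foreign compounds, 16 rose, 1 fell and 7 did not pass of 24 measured, with 16 and 2 adjusted over the list alone. The list was higher (camera adjusted p = 2.85e-10, and adjusted p = 0.0397 with an estimated correlation). Cyp2c55 (chromosome 19, 39007019 to 39042693) went from 11.4 ± 36.8 to 78.3 ± 53.8 CPM and Cyp3a11, a main drug-metabolising P450, from 3007 ± 1310 to 4958 ± 1810 CPM (log2 fold change 0.72 ± 0.13 SE, adjusted p = 7.85e-06). Cyp3a59 fell by 0.83 ± 0.25 on the log2 scale. Scores of this list lay above the vehicle median in 46 of 49 zileuton animals. Of AhR targets, which respond to the aryl hydrocarbon receptor, 3 rose, 0 fell and 7 did not pass of 10 measured, with 3 and 0 adjusted over the list alone. They passed camera narrowly (adjusted p = 0.0479, and adjusted p = 0.260 with an estimated correlation), in 42 of 90 fits without 1 library. Their score was above the vehicle median in 41 of 49 animals (adjusted permutation p = 5.67e-04). Cyp1a2 (chromosome 9, 57676937 to 57683703) rose 2.05-fold, from 684 ± 306 to 1399 ± 427 CPM (log2 fold change 1.03 ± 0.11 SE, adjusted p = 9.37e-13). It was above the vehicle median in 49 of 49 animals.

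Conjugation and antioxidant genes followed. Among NRF2 targets, the genes of the antioxidant response, 15 rose, 2 fell and 11 did not pass of 28 measured, with 19 and 2 adjusted over the list alone. As a list they were higher (camera adjusted p = 5.30e-07, and adjusted p = 0.0919 with an estimated correlation). The glutathione transferases Gstm3 (1.85 ± 0.39) and Gsta1 (1.53 ± 0.30) rose most on the log2 scale, while Osgin1 (−0.96 ± 0.17) and the autophagy receptor Sqstm1 (−0.21 ± 0.046) fell. In the phase II conjugation list, 13 rose, 2 fell and 16 did not pass of 31 measured, with 14 and 2 adjusted over the list alone. This list was higher too (camera adjusted p = 1.75e-04, and adjusted p = 0.0919 with an estimated correlation). Gstp1 rose from 237 ± 115 to 465 ± 170.3 CPM (0.97 ± 0.11) and Gstt2 by 0.68 ± 0.11, against −0.33 ± 0.093 for the sulfotransferase Sult2a8 and −0.22 ± 0.049 for the glucuronosyltransferase Ugt2a3. List scores were above the vehicle median in 44 of 49 animals for NRF2 targets and 42 for phase II conjugation.

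Fatty acid oxidation genes were higher. Of the targets of PPARalpha, the receptor that drives peroxisomal and mitochondrial fatty acid oxidation, 27 rose, 1 fell and 10 did not pass of 38 measured, with 30 and 1 adjusted over the list alone. They were higher as a list (camera adjusted p = 1.17e-15, and adjusted p = 0.0919 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase, rose from 628 ± 695 to 2246 ± 1595 CPM (log2 fold change 1.84 ± 0.31 SE, adjusted p = 1.25e-06) and Cyp4a31 by 1.91 ± 0.38, whereas Pdk4, a kinase that shuts pyruvate out of oxidation, fell by 1.00 ± 0.19. The score was above the vehicle median in 42 of 49 zileuton animals. Cd36, a fatty acid transporter in a list with 3 measured members that was too short to test, rose by 0.66 ± 0.15 (adjusted p = 2.27e-04), and the others, of the pancreas and adipose genes, did not pass.

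Genes of cell division were higher with zileuton. In the cell cycle list 22 rose, 0 fell and 6 did not pass of 28 measured, with 23 and 0 adjusted over the list alone. The list passed camera (adjusted p = 1.17e-15, and adjusted p = 0.0919 with an estimated correlation), with a median log2 fold change of 1.12. Cdc20, an activator of mitotic exit, rose from 0.785 ± 1.99 to 3.09 ± 5.91 CPM (log2 fold change 2.03 ± 0.36 SE, adjusted p = 5.56e-06), and the cyclin Ccnb2 from 0.415 ± 0.779 to 1.60 ± 2.43 CPM (log2 fold change 2.01 ± 0.31 SE, adjusted p = 2.21e-07). Without vehicle replicate 15, the library with the highest cell cycle score of its group, Cdc20 stood at 2.67. The cell cycle score was above the vehicle median in 46 of 49 animals. Levels were low, with group means of 4 such genes (Cdc20, Ccnb2, Hmmr, Ckap2) at most 3.09 CPM.

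**Figure D2:**
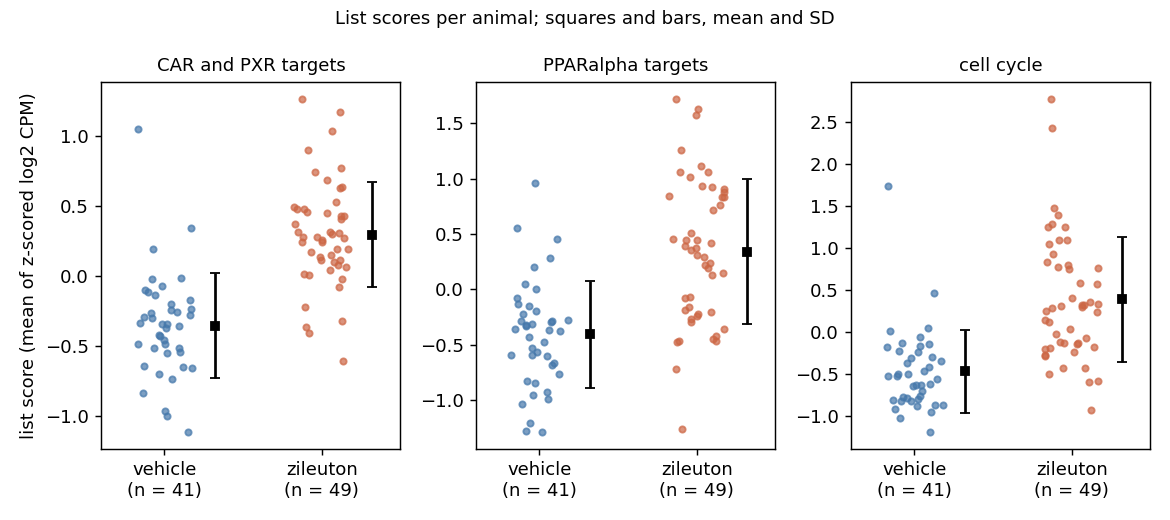
List score per animal (mean over members of log2 CPM scaled to unit SD over 90 animals, no unit) for CAR and PXR targets, PPARalpha targets and the cell cycle list, in 41 vehicle and 49 zileuton animals, with squares and bars for mean and SD. Zileuton scores lay above the vehicle median in 46, 42 and 46 of 49 animals.

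Circadian clock genes differed in opposite directions by phase. In this list 13 rose, 5 fell and 1 did not pass of 19 measured, with 13 and 5 adjusted over the list alone. As a whole the list was higher (camera adjusted p = 0.00116, and adjusted p = 0.0919 with an estimated correlation), and the list score lay above the vehicle median in 48 of 49 animals (adjusted permutation p = 4.29e-05). However, it held 5 genes that peak with Bmal1 and 11 of the opposite phase. A difference between these phases can therefore raise the list as a whole. Genes that peak with Bmal1 were lower, among them Arntl (chromosome 7, 113207465 to 113314126), which fell from 22.6 ± 8.13 to 6.82 ± 5.74 CPM and was below the vehicle median in 49 of 49 animals. Others of this phase were Npas2, Nfil3 (−1.17), Cry1 (−0.93) and Clock (−0.38). Genes of the opposite phase were higher, among them Ciart (chromosome 3, 95878503 to 95882251, 0.907 ± 2.06 to 6.28 ± 5.78 CPM), Dbp, Usp2, Per3 (1.81) and Per1 (1.16). A clock score, the mean scaled log2 CPM of opposite-phase genes minus that of Bmal1-phase genes, was −1.32 ± 1.27 (SD) in vehicle and 1.11 ± 1.17 in zileuton animals. Of the 49 zileuton animals, 48 lay above the vehicle median.

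Animal numbers were arranged by group. Within runs of 50 consecutive numbers, vehicle animals held positions 13 to 20 and zileuton animals 25 to 50. Across the 49 zileuton animals the clock score rose with this position (r = 0.434, permutation p = 0.00205, and rho = 0.443, p = 0.0018), with r = 0.402 without the 2 animals farthest from the median position and r = 0.428 with run removed. Within the 5 runs of at least 6 zileuton animals, r was 0.717, −0.130, 0.666, 0.736 and 0.767, and the other 3 runs held too few. Across 41 vehicle animals r was −0.105 (permutation p = 0.514, rho = −0.214, p = 0.178). Over these 2 relations the adjusted p was 0.00410 for zileuton and 0.514 for vehicle. As covariates in the main comparison, chosen after seeing the data, the clock score left 384 genes called and the position 217. With the clock score, camera no longer placed AhR targets, phase II conjugation, cholesterol synthesis, the unfolded protein response or the circadian list, from whose members the score was built, past the threshold, and with the position, AhR targets, cholangiocyte markers, plasma proteins, the circadian list and the unfolded protein response. Newly past it with the clock score were MHC class II genes (lower, adjusted p = 0.00118), p53 targets (higher, 0.00164) and heat shock genes (higher, 0.00168). With the position these were p53 targets (higher, 0.0420) and the integrated stress response (higher, 0.0155). All these new calls come from camera with its preset correlation, and an estimated one was not tried with either covariate.

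**Figure D3:**
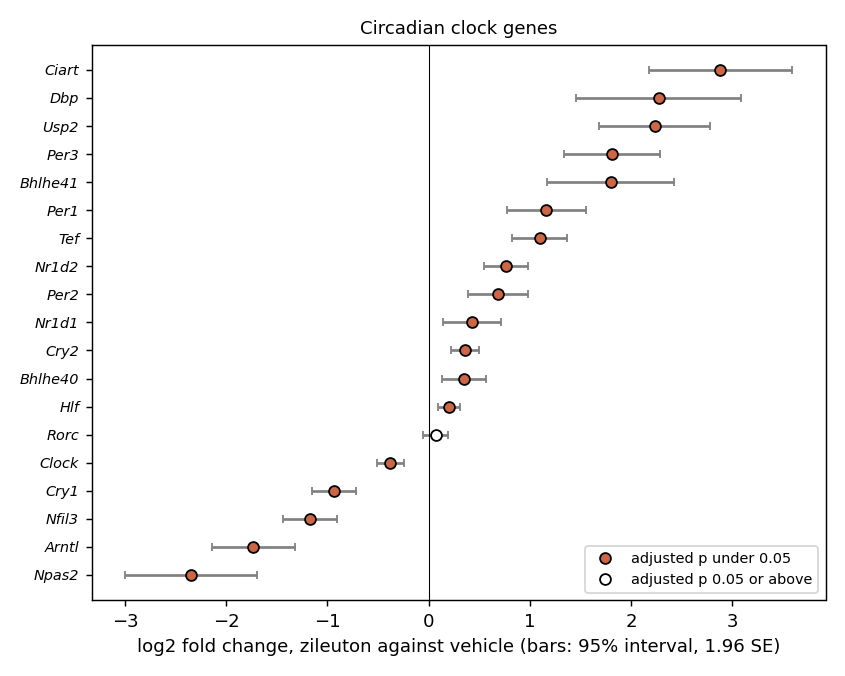
Log2 fold change of 19 circadian clock genes, zileuton against vehicle (horizontal axis), with bars of the 95% interval and filled points at adjusted p under 0.05. Npas2 and Arntl lay lowest and Ciart and Dbp highest.

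**Figure D4:**
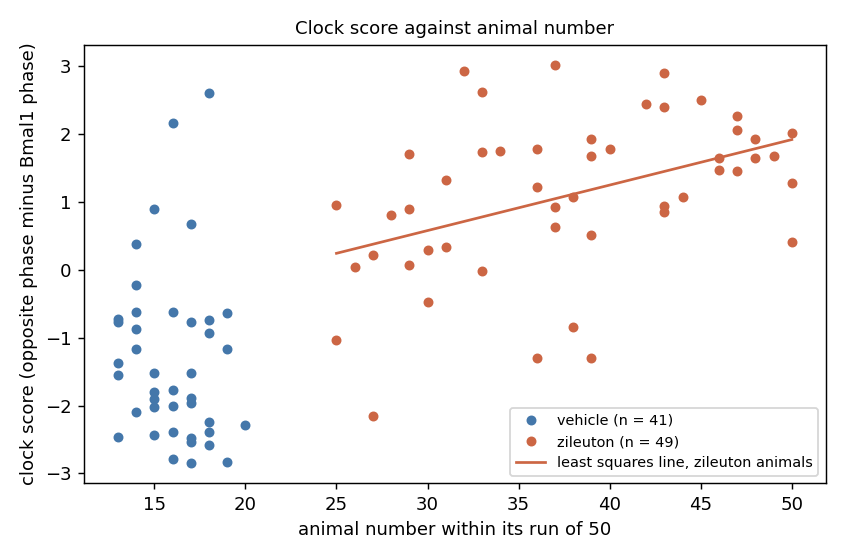
Clock score (vertical axis, scaled log2 CPM, opposite phase minus Bmal1 phase) against the animal's position in its run of 50 numbers, with 1 point per animal and a least squares line for the 49 zileuton animals. Vehicle animals sit at positions 13 to 20 and zileuton animals at 25 to 50.

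Genes of protein folding and secretion fell. In the unfolded protein response list 0 rose, 16 fell and 4 did not pass of 20 measured, with 0 and 16 adjusted over the list alone. The list was lower (camera adjusted p = 2.99e-05, and adjusted p = 0.454 with an estimated correlation). Sdf2l1 went from 30.1 ± 25.0 to 15.9 ± 8.49 CPM (log2 fold change −0.92 ± 0.17 SE, adjusted p = 1.06e-05), and Creld2, like it a folding factor of the endoplasmic reticulum, changed by −0.85 ± 0.19. Among plasma proteins 2 rose, 18 fell and 8 did not pass of 28 measured, with 2 and 18 adjusted over the list alone. These were lower as a list (camera adjusted p = 1.04e-04, and adjusted p = 0.265 with an estimated correlation). Serpina1e (−1.34 ± 0.35) and the complement gene C9 (−0.57 ± 0.15) fell, and complement C3 rose (0.32 ± 0.092). List scores lay above the vehicle median in 9 of 49 zileuton animals for the first list and 8 for the second.

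Lists of amino acid, lipid and glucose metabolism held genes that moved both ways. In the amino acid and urea list 2 rose, 10 fell and 14 did not pass of 26 measured, with 2 and 10 adjusted over the list alone. Bhmt was at −0.49 ± 0.11, Gls2 at −0.44 ± 0.084 and Sds at 0.55 ± 0.13 (camera adjusted p = 0.0182, adjusted p = 0.833 with an estimated correlation, and 0.0572 for the permuted score). In cholesterol synthesis 4 rose, 1 fell and 20 did not pass of 25 measured, with 4 and 1 adjusted over the list alone. Srebf2, which activates this pathway, was at −0.20 ± 0.048 (camera adjusted p = 0.0479, adjusted p = 0.942 with an estimated correlation, and 0.228 for the permuted score), and the list passed in 50 of 90 fits without 1 library. Fatty acid synthesis (5 rose, 3 fell and 14 did not pass of 22 measured, with 6 and 7 adjusted over the list alone) did not pass (camera adjusted p = 0.841), with Thrsp at 0.93 ± 0.18 and Agpat2 at −0.53 ± 0.064. Bile acid synthesis and transport (5 rose, 5 fell and 12 did not pass of 22 measured, with 5 and 7 adjusted over the list alone) did not pass either (0.882), although the export pumps Abcc2 (0.50 ± 0.077) and Abcb11 (−0.35 ± 0.064) changed in opposite directions. Glucose metabolism (3 rose, 6 fell and 10 did not pass of 19 measured, with 5 and 6 adjusted over the list alone, adjusted p = 0.841) held Pfkfb3 at 1.28 ± 0.20 and G6pc, which releases glucose, at −0.85 ± 0.18. Sex-biased and growth hormone responsive genes (4 rose, 8 fell and 13 did not pass of 25 measured, with 5 and 8 adjusted over the list alone, adjusted p = 0.866) had a median of −0.09 and a mean of 0.03, with Cyp4a12a and Mup20 (1.15 ± 0.22) up and A1bg (−1.31 ± 0.39) and Serpina12 (−1.26 ± 0.36) down.

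The drug target was scarcely expressed in these livers. Alox5, which encodes 5-lipoxygenase, averaged 0.0826 CPM in vehicle and 0.0663 CPM in zileuton animals and was too low to test. Its partner Alox5ap was at 2.08 and 1.90 CPM (log2 fold change −0.13 ± 0.16 SE, adjusted p = 0.609). Among lipoxygenase and eicosanoid genes 4 rose, 2 fell and 16 did not pass of 22 measured, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.844, direction up against a median of −0.04), with Ephx2, an epoxide hydrolase, at 0.44 ± 0.13.

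Genes of injury and stress changed in part. Gpt and Got1, whose enzymes are measured in serum as signs of liver injury, were at log2 fold change 0.05 ± 0.060 and −0.06 ± 0.13 (adjusted p = 0.610 and 0.765). In the liver injury list 2 rose, 1 fell and 14 did not pass of 17 measured, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.946, median 0.05 and mean −0.04), with Tubb2a at −1.26 ± 0.18, Myc at 0.65 ± 0.16 and Krt8 at 0.24 ± 0.064. The integrated stress response (4 rose, 4 fell and 12 did not pass of 20 measured, with 5 and 4 adjusted over the list alone, adjusted p = 0.882) held Ddit4 at 0.94 ± 0.24 (0.37 and adjusted p = 0.222 with run as a covariate, and above the vehicle median in 25 of 49 animals), Trib3 at 0.73 ± 0.16, Atf5 at −0.75 ± 0.081 and Fgf21. For p53 targets 5 rose, 1 fell and 13 did not pass of 19 measured, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.250, and 0.0411 for the permuted score), with Ccng1 at 0.25 ± 0.068 and Bbc3 at −0.28 ± 0.089. Heat shock genes (2 rose, 1 fell and 11 did not pass of 14 measured, with 2 and 1 adjusted over the list alone, adjusted p = 0.882, direction up against a median of −0.06) held the chaperonin gene Hspd1 at 0.19 ± 0.041 and Bag3 at −0.38 ± 0.11.

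Inflammation and the other cell types of the liver were followed through marker lists. The acute phase list (4 rose, 9 fell and 15 did not pass of 28 measured, with 4 and 9 adjusted over the list alone, camera adjusted p = 0.889) held Il1rn, an interleukin 1 antagonist, at 1.09 ± 0.17 beside the Saa genes. Interferon response genes (0 rose, 4 fell and 24 did not pass of 28 measured, with 0 and 3 adjusted over the list alone) were lower by camera (adjusted p = 0.0383) but not with an estimated correlation (adjusted p = 0.942) or by permuted score (0.148), and they passed in 75 of 90 fits without 1 library. Rsad2 was at −0.54 ± 0.18 and Isg15 at −0.37 ± 0.13. Lymphocyte markers (0 rose, 4 fell and 9 did not pass of 13 measured, with 0 and 6 adjusted over the list alone) were lower (camera adjusted p = 0.0264, and adjusted p = 0.655 with an estimated correlation), with the score above the vehicle median in 14 of 49 animals (adjusted permutation p = 0.00592). The 4 were Cd3g, Cd3d, Lck and Cxcr6, each with a mean below 1 CPM over all animals, while Klrk1 stood at −0.23 ± 0.18 (adjusted p = 0.339). Cholangiocyte markers (0 rose, 3 fell and 8 did not pass of 11 measured, with 0 and 3 adjusted over the list alone) were lower too (camera adjusted p = 0.00788, and adjusted p = 0.196 with an estimated correlation). Sox9 was at −0.86 ± 0.14, and the score was above the vehicle median in 5 of 49 animals.

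Other cell type lists did not pass. Camera gave adjusted p = 0.250 for MHC class II genes (0 rose, 0 fell and 7 did not pass of 7 measured, with 0 and 0 adjusted over the list alone), 0.946 for Kupffer cell and macrophage markers (0 rose, 1 fell and 14 did not pass of 15 measured, with 0 and 0 adjusted over the list alone) and 0.650 for monocyte and neutrophil markers (0 rose, 2 fell and 9 did not pass of 11 measured, with 0 and 2 adjusted over the list alone). It gave 0.841 for stellate cell and matrix genes (1 rose, 3 fell and 15 did not pass of 19 measured, with 1 and 3 adjusted over the list alone), 0.986 for endothelial markers (1 rose, 1 fell and 14 did not pass of 16 measured, with 1 and 1 adjusted over the list alone) and 0.841 for erythroid genes (0 rose, 0 fell and 8 did not pass of 8 measured, with 0 and 0 adjusted over the list alone). Cd74 stood at −0.18 ± 0.14 (adjusted p = 0.336), the stellate genes Pdgfrb and Dcn at −0.28 ± 0.071 and −0.21 ± 0.065, the endothelial genes Vwf and Clec4g at 0.37 ± 0.11 and −0.18 ± 0.064, and Hbb-b1 at −0.27 ± 0.19 (adjusted p = 0.280). The endothelial list had a median of 0.02 where camera gave the direction down.

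Whether zileuton changed the spread between animals was asked of 11857 genes. Ppard varied less with zileuton, with an SD of log2 CPM of 0.993 in 41 vehicle and 0.544 in 49 zileuton animals (adjusted p = 0.0158, limma on absolute deviations). Rhobtb1, Rlf and Gm6710 varied more, with SDs of 0.268 and 0.520, 0.174 and 0.323, and 0.889 and 1.34 in vehicle and zileuton animals (adjusted p = 0.0442 for each). Over all genes the median ratio of SDs, zileuton over vehicle, was 0.990. Leaving out 1 library ended the calls of Rhobtb1 and Rlf in 58 of 90 fits each and of Gm6710 in 57, and the number of calls ran from 1 to 11. With run removed, Rlf alone of these 4 passed (ratio of SDs 1.90, adjusted p = 0.0382), and Ppard did not (0.629, 0.276).

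Treatment accounted for 6.12% of the variance of log2 CPM between libraries (permutation p = 1e-04, the smallest that the permutations can give). Mean distance to the group centroid was 60.5 ± 5.36 (SD) in vehicle and 61.04 ± 4.20 in zileuton libraries, a difference of 0.501 (permutation p = 0.623). Over all tested genes, 3 vehicle and 4 zileuton libraries lay nearer the centroid of the other group.

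Coat colour, which follows recessive alleles at Tyr (white) and at the agouti locus (black), was compared as the label that tells animals apart genetically. Mup14, a major urinary protein gene, was higher in black than in agouti animals by 5.70 on the log2 scale (adjusted p = 2.39e-06), but stood at −0.01 without zileuton replicate 38, in which it reached 584 CPM. The muscle myosin gene Myh7b (−3.33, adjusted p = 3.37e-04) and Gm16223 (−3.32, 0.00117) were lower, Pigu (0.25, 0.0124) and Pou2af1 (1.35, 0.0410) higher and Phf20 (−0.42, 0.0207) lower, which makes 6 genes, with Pou2af1 named outside the rule after its value was seen. Without 1 library, Pigu lost its call in 3 of 90 fits and Phf20 in 6. White and agouti animals differed in 1 gene, Fhl3 (1.68, adjusted p = 0.00128), which stood at 0.16 (adjusted p = 0.950) without zileuton replicate 24, a library with skeletal muscle transcripts. Without single libraries, black gave 4 to 7 genes and white 0 to 23, the latter without vehicle replicate 8. With run added, 3 and 0 genes were called by edgeR, the latter with 774 genes at an unadjusted p under 0.05. DESeq2 without run called 4 black genes and 0 white, the latter with 948 genes at an unadjusted p under 0.05. Tyr itself averaged 0.0133 CPM in vehicle and 0.00874 CPM in zileuton animals and was not tested.

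No gene passed the test of whether the zileuton contrast differed by coat colour. The edgeR interaction test called 0 genes, with 737 at an unadjusted p under 0.05, and the DESeq2 likelihood ratio test called 0, with 775.

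Whether responses varied together between animals was asked of 28 pairs of 8 list scores within each arm, with p adjusted over both arms. In vehicle animals 1 pair passed, CAR and PXR targets with NRF2 targets (r = 0.667, permutation p = 2.00e-05, adjusted p = 3.73e-04, rho = 0.521, p = 5.70e-04, and r = 0.475 without 2 animals). In zileuton animals 10 pairs passed, 6 positive and 4 negative. Among them were NRF2 with PPARalpha targets (r = 0.674, permutation p = 1e-05, adjusted p = 2.80e-04, rho = 0.689, p = 1e-05, and r = 0.641 without 2) and cell cycle with plasma proteins (r = −0.526, permutation p = 1.20e-04, adjusted p = 0.00134, rho = −0.463, p = 8.80e-04, and r = −0.496 without 2). A permutation p of 1e-05 is the smallest these tests can give. With run removed from the scores, 0 zileuton pairs (7 at an unadjusted permutation p under 0.05) and 1 vehicle pair (r = 0.714) passed. The zileuton relations were weaker then, with r = 0.151 (permutation p = 0.299, adjusted p = 0.548) for the first pair and −0.347 (permutation p = 0.0151, adjusted p = 0.139) for the second, which kept its sign. The difference in r between arms passed in 0 of 28 pairs, with 3 at an unadjusted p under 0.05 by permutation.

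Library measures differed between groups in the share of counts on the most abundant genes. The 10 largest genes of a library took 21.7% ± 2.51 (SD) of counts in vehicle and 20.3% ± 2.01 in zileuton animals (permutation p = 0.00264, adjusted p = 0.00792 over 6 measures). Albumin (Alb), a measure added after seeing the data, took 9.94% ± 1.503 and 8.66% ± 1.66 (adjusted p = 0.00156). Total counts (adjusted p = 0.653), genes detected (adjusted p = 0.745), haemoglobin (0.0492% and 0.0416%, adjusted p = 0.483) and Rn45s (2.65% and 2.89%, adjusted p = 0.653) did not pass. The 2 libraries with skeletal muscle transcripts, vehicle replicate 8 and zileuton replicate 24, held 4912 and 3008 CPM over 16 muscle genes, against at most 23.1 CPM in any other library.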

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

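The measures of Fhl3, Mup14, detected genes and shares of counts were looked at for single libraries far from the rest of their coat colour and treatment group, and the tests of these genes, of muscle markers and of list medians in other splits were chosen only after the result was seen. Of 40 groups of values examined, 6 held such a library, where normally distributed values would give about 1 in 20, or 2.0 groups. The values were not put on a log scale, and the genes were chosen by the coat colour tests on the same libraries. The 2.0 groups are therefore no chance rate for these values. The measure was the gap to the nearest other library divided by the whole range of the group.

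Among 9 white zileuton animals, zileuton replicate 24 held 17.8 CPM of Fhl3, a gene of skeletal muscle, against 1.27 in the next (ratio 0.939), and 16727 detected genes against 16126 (ratio 0.507). Zileuton replicate 38, among 6 black zileuton animals, held 584 CPM of Mup14 against 5.37 (ratio 0.991). Zileuton replicate 23, among the white zileuton animals, held 3.35 CPM of Mup14 against 1.66 (ratio 0.505). In 6 black vehicle animals, vehicle replicate 22 had 32.2% of counts on its 10 largest genes against 22.5% (ratio 0.775), and 14.04% of its counts were on Rn45s. The share of haemoglobin in vehicle replicate 26, a white animal, was 0.0649% against 0.0371% (ratio 0.627).

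The muscle marker list of 16 genes was written after zileuton replicate 24 stood apart. Acta1 and Ckm, abundant in muscle fibres, reached 1486 and 449.7 CPM in vehicle replicate 8 and 974 and 403 CPM in zileuton replicate 24. Without both libraries, the main comparison called 3832 genes.

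Other groupings of the same libraries were counted for each comparison. The 3878 genes called between zileuton and vehicle were matched by 1 of 100 splits of the libraries, the real one. The others gave at most 89 and a median of 10, so chance can be excluded for this count. For gene lists 6 of 100 splits gave 14 or more. Splits other than the real one gave up to 16, with a median of 8, so chance cannot be excluded for the number of lists. The medians of CAR and PXR, NRF2 and PPARalpha targets, phase II conjugation, cholangiocyte markers, the cell cycle, the unfolded protein response, plasma proteins and the circadian clock each lay farther from 0 than in any other split. For the spread between animals, 1 of 100 splits gave 4 or more genes, the highest other being 0. Differences in level between zileuton and vehicle stayed in the values of the other splits. These splits are therefore no test of equal spread, and chance cannot be excluded for this count. It was not stable, with 0 genes by limma without libraries over 5% Rn45s (984 at an unadjusted p under 0.05) and 1 without muscle libraries. Coat colours permuted within treatment gave as many genes in 27 of 50 splits for white (real 1, highest other 124), 13 of 50 for black (real 6, highest other 32) and 50 of 50 for the interaction (real 0, highest other 49), so chance cannot be excluded for these. Some splits called many times the real count of coat colour genes, which points to a structure among the libraries other than coat, whose source was not tested.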

How the results depend on the processing

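Tests with the clock score, the animal number within its run, Rn45s, muscle transcripts, libraries on the other side and single libraries left out were chosen only after the result was seen. The permutation test of list scores was not planned beforehand either. Under 29 other settings of the main comparison, apart from the clock score and the number within run, 3142 to 4163 genes were called. Over 110 genes that the rule chose for the main comparison and lists, those settings gave 3189 values, of which 3035 kept direction and side, 153 were no longer past the threshold, 0 were newly past and 1 changed sign. The lowest count came with library plate column as a covariate, where 2981 of the 3878 calls were kept. Plate columns were not balanced between the groups, with zileuton libraries more often in the higher-numbered columns. Depth limits genes near the floor, such as Alox5 and Tyr.

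With the clock score as a covariate the 3878 calls became 384 (239 higher, 145 lower, 68 at least 2-fold), and 76 of 104 called genes among these no longer passed. With the animal number within run they became 217 (166 higher, 51 lower, 87 at least 2-fold). The standard error rose by a median ratio of 1.39 and 2.15, and the log2 fold change moved to a median ratio of 0.564 and 0.742 of its value. These covariates follow the groups (r = 0.708 and 0.886). Without a low-count filter 593 genes changed at least 2-fold, from more genes tested. Camera with an estimated correlation kept 1 list. The spread count was 9 at an average log2 CPM of at least 3, 2 with library size only, 0 by limma without libraries over 5% Rn45s (984 at an unadjusted p under 0.05) and 1 without muscle libraries. White gave 0 genes with DESeq2 (948 at an unadjusted p under 0.05) and with edgeR with run added (774), with vehicle libraries only (604) and without muscle libraries (867), and 32 with zileuton libraries only. Black gave 3 with run added, 2 with vehicle libraries only and 1 with zileuton libraries only. Correlated pairs were 4 in vehicle animals with library size only and 0 in zileuton animals with run removed (7 at an unadjusted permutation p under 0.05). Apart from these constructions, the cause was not tested.

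Among the reported values past the threshold before or after a change of setting, 7 turned direction, 1 of them past it after the change, and lists that did not pass turned too. With the clock score 349 of the 3878 calls had the other sign, and 474 with the number within run. The circadian list had adjusted p = 0.902 with the clock score, which is built from its members, and the integrated stress response 0.0155, now past the threshold, with the number within run (range over settings 0.0155 to 0.994). Log2 fold changes were 0.021 for Ankrd23 without run 2, 0.17 for Pdk4 and 0.17 for Serpina12 with the number within run, 0.070 for Tubb2a with the clock score and −1.90 for Mup14 in black animals with vehicle libraries only. Without 1 library in turn, calls ran from 3752 to 4085 (1851 to 2024 higher, 1892 to 2069 lower, 179 to 202 at least 2-fold), lists from 11 to 14 (AhR targets, cholesterol synthesis and interferon response not always among them), spread from 1 to 11, white from 0 to 23 and black from 4 to 7. Of those called genes, 9 lost the call in at least 1 such fit: Ankrd23, Btg2, Col1a1, Cyp1a1, Fetub, Il1b, Il1r1, Msmo1 and Slc40a1. Gm6710 and Mup14, chosen for spread and coat, lost their zileuton calls in 41 and 1.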

Other observations

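The tests of clock phases, of libraries on the other group's side and of clock-adjusted lists were chosen only after the result was seen. So was the test of CAR and PXR placement against the clock score. So were all values here with the clock score or the animal number within its run as a covariate.

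With the clock score as a covariate, the lists parted. CAR and PXR targets (camera adjusted p = 2.69e-07), NRF2 targets (9.82e-05), PPARalpha targets (4.21e-07) and the cell cycle (7.68e-13) stayed higher by camera with its preset correlation, of which only the first passed with an estimated correlation in the main comparison (NRF2 targets 0.0919, PPARalpha targets 0.0919 and cell cycle 0.0919). Plasma proteins (5.29e-07), lymphocyte markers (3.51e-06), amino acid and urea metabolism (1.41e-04), the interferon response (5.86e-04) and cholangiocyte markers (0.0344) stayed lower, and none of these passed with an estimated correlation (adjusted p = 0.265 for plasma proteins). The unfolded protein response (0.736), phase II conjugation (0.0987), AhR targets (0.414) and cholesterol synthesis (0.131) no longer passed, while MHC class II genes (0.00118, lower), p53 targets (0.00164, higher) and heat shock genes (0.00168, higher) newly did. In the main comparison these last had adjusted p = 0.942, 0.727 and 0.995 by camera with an estimated correlation, although p53 targets passed fry (0.0338). An estimated correlation was not tried with the clock score. The circadian list (0.902) decides nothing here, since the score was built from its members. Over all other settings, with fry (a test against no change) among them, adjusted p ran from 7.38e-13 to 0.0397 for CAR and PXR targets, 5.10e-18 to 0.0919 for the cell cycle, 5.29e-07 to 0.618 for plasma proteins and 1.03e-05 to 0.736 for the unfolded protein response. With the clock score, Cyp2c29 stood at 1.17 (adjusted p = 5.90e-06), Cyp2c55 at 1.69 (0.00325), Cyp1a2 at 0.55 (0.00417) and Dnmt3b at −0.49 (0.0196), while Cyp3a11 at 0.50 (0.109), Gstm3 at 0.95 (0.196), Cyp4a12a at 2.01 (0.0848) and Ppard at −0.15 (0.674) no longer passed.

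The clock genes differed between the groups. The medians of the 2 phases were −1.17 and 1.16, a difference of 2.33. Clock genes act on each other, so a change in 1 part of the clock could also move both phases. This difference therefore cannot tell such a change from a shift of the whole cycle. If animals were sampled in order of their numbers, zileuton livers may have been taken later in the day than vehicle livers. The slope of the score on position among zileuton animals covered 60.4% (95% bootstrap interval 28.9 to 92.0) of the group difference, and across the 3878 called genes the slope and the log2 fold change correlated at 0.459, as high in 4 of 100 permutations of the numbers, although genes are not independent replicates and clock genes are among them. An effect of zileuton on the clock stays open, since positions do not overlap between groups and sampling times were not used here.

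Cell cycle genes were higher with zileuton, a candidate explanation being hepatocyte division, for which no test was run. More immune or other cells would raise their markers, but 0 of 6 marker lists came near the cell cycle median, the highest being at 0.02 against 1.12. Division within an unchanged number of such cells would leave their markers level. With cell cycle genes this low, a small number of dividing cells of any type stays open too. Under 3 other scalings at least 99.2% of that median was kept, and 93.9% of zileuton animals lay above the vehicle median score, which argues against scaling and against a few extreme animals. With the clock score as a covariate 76.1% of the median was kept (0.85), and with the number within run 121% (1.35), so a share due to time of sampling cannot be told apart, because both covariates follow the groups.

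Libraries on the other group's side were counted by distance to the group centroids, each left out of its own. Over all tested genes 3 vehicle and 4 zileuton libraries lay nearer the other group, and 2 did so in each of 5 gene sets, vehicle replicate 15 and zileuton replicate 26. A swap of these 2 labels may account for them: vehicle replicate 15 had 6577 CPM of Cyp2c29 and a clock score of 2.17, and zileuton replicate 26 had 3065 CPM and −1.31. It leaves out 3 others that crossed in 4 of the 5 sets, vehicle replicates 28 and 37 (4914 and 16851 CPM) and zileuton replicate 28 (7238 CPM). Were time of sampling the cause for all libraries that crossed in all genes and the clock list, CAR and PXR targets would stand where the clock score puts them in the libraries that did not cross. There their placement correlated with the clock score at r = 0.191 (permutation p = 0.252, adjusted p = 0.252, rho = 0.164, p = 0.325, and r = 0.0289 without 2) in 38 vehicle and 0.384 (permutation p = 0.00901, adjusted p = 0.0180, rho = 0.388, p = 0.00848, and r = 0.345 without 2) in 45 zileuton animals. Of 5 such libraries, 3 lay outside the 95% prediction interval of that line (vehicle replicates 15 and 37 and zileuton replicate 26, binomial p = 0.00116). All tested genes include the CAR and PXR targets, and the line was drawn through libraries chosen because they did not cross. The chance share behind this binomial p therefore does not hold, and the test cannot decide whether time of sampling was the only cause. For the 2 inside the interval, vehicle replicate 28 and zileuton replicate 28, time of sampling cannot be told apart either, since no sampling times were used here. Vehicle replicates 15 and 28 had clock scores beyond those of the line. A weak response to the drug stays open for zileuton replicates 26 and 28 only. It cannot account for vehicle replicates 15, 28 and 37, which as labelled were given no zileuton. Without vehicle replicate 15 and zileuton replicate 26, 4163 genes were called, a count that is circular since they were chosen by the outcome.

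Black coats and nearby genes were compared at the agouti locus. Of the 6 genes called between black and agouti animals, 3 (Myh7b, Pigu and Phf20) lay within 10 Mb of the locus (chromosome 2, 154791402 to 155051012). Fisher's exact test gave p = 3.69e-05 and an odds ratio of 80.7. It treats genes as independent, which neighbours measured in the same animals are not, so this p overstates the evidence. Linked founder haplotypes in black animals may account for these genes. Genes at an unadjusted p under 0.05 made up 13.9% near the locus and 6.44% elsewhere.

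The same test at Tyr (chromosome 7, 87424771 to 87493512) found 0 of 1 called gene within 10 Mb (Fisher's exact p = 1), too few to decide, with 18.2% of genes near the locus and 6.92% elsewhere at an unadjusted p under 0.05.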
